A study of Glycine max with 12 samples.

How the data were processed

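RNA was measured in 12 sequencing libraries of field-grown soybean (Glycine max) by RNA-seq. Per the labels, the material was seed from 3 to 5 plants, RNA was extracted with a column kit and treated with DNase, and libraries followed a standard Illumina protocol. The plants were the cultivar Thorne and 2 gene-edited lines derived for the major seed protein locus on chromosome 20, a single mutant in the chromosome 20 gene and a double mutant that also carries an edit in its paralog on chromosome 10. Each genotype was sampled at 2 stages labelled R5 and V5, with 2 libraries per genotype and stage, which makes 6 groups. R5 is the name soybean growers use for the start of seed filling, and V5 is the name of a vegetative stage before flowering, while the labels give seed as the tissue of every library. The stage names are therefore used here only as labels.

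The authors deposited 1 table per library with a whole-number read count for each of 56044 gene IDs. Per the submitters' processing notes, Bowtie, HISAT2 and HTSeq were used, with no role, order or version given. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Soybean keeps many near-identical gene copies, so reads of paralogs may have been split, shared or dropped in the counting, and the counts of the edited pair are uncertain for the same reason. The total count was 26966329 to 34626177 per library at R5 and 20410270 to 21066989 at V5, and 38977 to 42721 genes had at least 1 count. A total of 7873 IDs had 0 counts in every library. Intervals and floors given for counts cover counting error only, since the reads carry no molecular identifiers.

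The deposited counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and removal of low genes with filterByExpr (minimum count 10, minimum total count 15). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each of the 6 comparisons between genotypes within a stage was fitted on the 6 libraries of that stage, which leaves 3 residual degrees of freedom. The change of each mutant's difference from wild type between the stages, and the comparison of the stages in wild type, were fitted on all 12 libraries with 6 residual degrees of freedom. A log2 fold change has its standard error in parentheses. Levels are CPM values, the count of a gene scaled to a common library total, as mean ± SD. The labels do not say that the 2 libraries of a group come from separate plots or plants, so p-values measure the spread between these samples, which may be technical.

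The groups, the tests and the first set of alternatives were fixed before the data were examined. The alternatives were median-of-ratios size factors (RLE) in edgeR, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each library left out in turn, all 12 libraries in 1 fit and only the 4 libraries compared. Alternatives added after the data were seen were limma 3.58.1 (voom with sample quality weights), edgeR with its newer dispersion method, DESeq2 and limma fits without the single mutant V5 replicate 2, a DESeq2 fit without its replicate 1, fold bounds after TMM scaling, fits without the double mutant R5 replicate 1 and the single mutant R5 replicate 2, a term for those 2 R5 libraries, and a crossed pairing at R5. The correlation between stages and the chromosome test were run without the single mutant V5 replicate 2 and again with all 6 V5 libraries. DESeq2 leaves the adjusted p of some genes undefined, and these were not counted as calls.

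The files do not pair gene IDs with names. None of the 56044 IDs matched the reference table of 59048 genes (0 matches), so genes appear by ID alone. The 24 gene lists fixed beforehand were defined by product descriptions and 0 of them could be filled, so no gene list was tested. The rule fixed beforehand for named genes took called genes with a mean log2 CPM of 1 or more, without overlap between the groups, ranked by log2 fold change (8 per direction against wild type, fewer elsewhere). At most 2 IDs per direction are printed for each comparison. Where no gene was called, the IDs printed are those with the smallest unadjusted p under the same conditions, and they were chosen after their values were seen. The labels name the edited locus but no gene ID. The IDs used for the edited pair, Glyma.20G085100 and Glyma.10G134400, come from background knowledge of the locus and were fixed before the data were examined.

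The fitting code was tested on simulated counts drawn from the means, library sizes and spread of the real libraries, with 200 genes changed (100 of them 4-fold and 100 of them 16-fold). At R5, 67% of the 4-fold and 95% of the 16-fold changes were recovered for the double mutant against wild type among 36596 genes, and 61% and 99% for the single mutant among 36565. At V5 the recovery was 2% and 66% for the double mutant among 33140 genes and 3% and 61% for the single mutant among 33201. Without the single mutant V5 replicate 2 it was 100% at both sizes for the double mutant among 33521 genes, with 37 false calls. For the stages in wild type it was 32% and 86% among 37612 genes. The simulated spread was the fitted one, so recovery in the real libraries can be lower. In the real double mutant at V5 without the single mutant replicate 2, log2 fold changes of 3.28 (Glyma.18G294200) and -4.36 (Glyma.06G149100) were not called. The recovery of 100% was therefore not reached there, and a lack of calls does not show that 4-fold changes were absent. Comparisons against the same wild-type libraries share their chance values. Unchanged mutants were therefore simulated against the same wild-type libraries, 20 times for correlations and 5 times for DESeq2 calls.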

Results

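Transcript levels were measured in material labelled as seed, from the soybean cultivar Thorne and 2 edited lines. The question was how editing the gene of a major seed protein locus, alone or with its paralog, changed the transcriptome. Wild type, the single mutant and the double mutant each had 2 libraries labelled R5 and 2 labelled V5. The 6 R5 libraries held 26966329 to 34626177 counts each and the 6 V5 libraries 20410270 to 21066989.

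The edited genes were read first. At R5 the chromosome 20 gene, Glyma.20G085100, had 0 to 4 counts per library and the chromosome 10 gene, Glyma.10G134400, had 0 to 6, which is too few for a test. At V5 Glyma.20G085100 had 10 to 31 counts, with 0.806 ± 0.0315 CPM in wild type, 1.25 ± 0.346 CPM in the double mutant and 0.983 ± 0.719 CPM in the single mutant (SD, n = 2 each). At the same stage Glyma.10G134400 had 19 to 67 counts, with 1.69 ± 0.456 CPM in wild type, 1.06 ± 0.209 CPM in the double mutant and 2.42 ± 1.14 CPM in the single mutant (SD, n = 2 each). The log2 fold change of Glyma.10G134400 in the double mutant was -0.97 (SE 0.59) against wild type and -1.16 (SE 0.59) against the single mutant, with edgeR adjusted p of 1 and 0.669. For Glyma.20G085100 it was 0.31 (SE 0.76) in the double and -0.04 (SE 0.76) in the single mutant against wild type, with edgeR adjusted p of 1 and 0.985. A small edit in the coding sequence need not change the RNA level, so these values do not check the genotype labels. The Glyma.20G085100 value in the single mutant at V5 was 0.69 without the single mutant replicate 2 and -1.46 without its replicate 1. In the double mutant it was -0.01 without the double mutant replicate 1 and 0.58 without its replicate 2. The value of -1.16 for Glyma.10G134400 was -1.72 without the single mutant replicate 2 and -0.21 without its replicate 1.

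**Figure D1:**
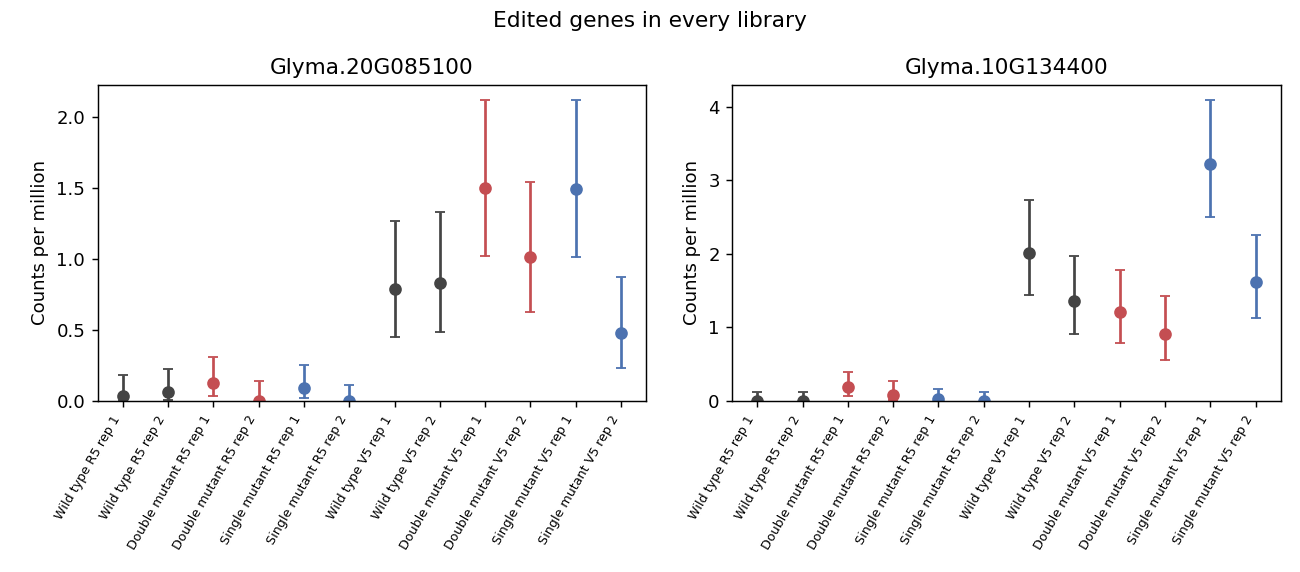
CPM values of the edited genes in each of the 12 libraries (points), with exact Poisson 95% intervals for counting error. Glyma.20G085100 had 0 to 4 counts at R5 and 10 to 31 at V5, and Glyma.10G134400 had 0 to 6 and 19 to 67.

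The libraries labelled R5 and V5 had different transcriptomes. In wild type 14558 of 38559 genes differed, 8040 higher at R5 and 6518 lower. Glyma.07G115500 reached 751 ± 134 CPM and Glyma.09G278000 reached 408 ± 255 CPM in wild type at R5 (SD, n = 2 each), and both had 0 counts in wild type at V5, which makes them at least 5120-fold and 2780-fold higher at R5 in CPM against a floor of 3 counts per library, and at least 2730-fold and 1480-fold after TMM scaling. Their edgeR adjusted p was 0.00087 and 0.00948. Glyma.13G194400 reached 24700 ± 2240 CPM and Glyma.13G123500 reached 19500 ± 7390 CPM at V5 (SD, n = 2 each), with 0 counts in wild type at R5, and were at least 259000-fold and 204000-fold higher at V5 in CPM, and at least 443000-fold and 354000-fold after TMM scaling. Their edgeR adjusted p was 0.0046 and 0.00285. Over both stages, 299 genes were above 1 CPM in all 6 V5 libraries and at 0.1 CPM or less in all 6 R5 libraries, and 391 genes showed the opposite. The count of called genes fell to 7479, 7813, 7228 and 7016 when wild-type R5 replicate 1, R5 replicate 2, V5 replicate 1 or V5 replicate 2 was left out, and it was 21801 and 21813 without the single mutant V5 replicate 1 or replicate 2.

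A few genes supplied much of the RNA at V5. The 20 genes most abundant at V5 held 38.7% ± 4.2 of all counts in wild type and 28.3% ± 0.0126 in the double mutant (SD, n = 2 each). In the single mutant they held 29.8% in replicate 1 and 2.58% in replicate 2. Of these genes, 8 had 0 counts in all 6 R5 libraries, and none had more than 142 counts in any R5 library.

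**Figure D2:**
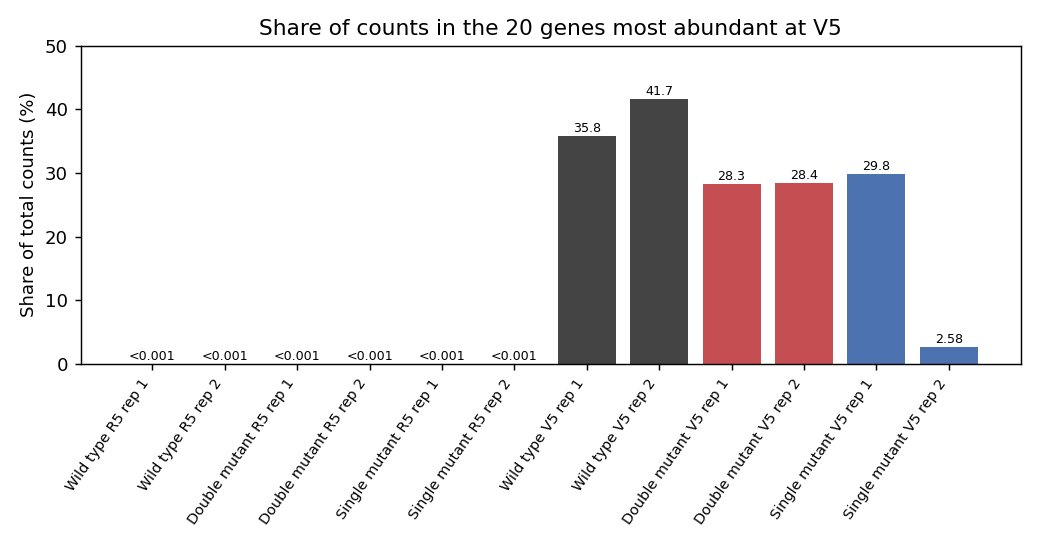
Share of total counts, in percent, held by the 20 genes most abundant at V5 in each library (bars, 1 library each). The share was 35.8% and 41.7% in wild type, 28.3% and 28.4% in the double mutant, and 29.8% and 2.58% in the single mutant at V5.

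The single mutant V5 replicate 2 stood apart from the other V5 libraries. The spread of log2 count ratios over 7179 abundant genes was 1.278 to 1.382 between it and the other 5, and 0.143 to 0.281 among those 5. At R5 the closest pair was the double mutant replicate 1 and the single mutant replicate 2, with a spread of 0.089 over 14380 abundant genes, against 0.235 between the wild-type replicates, 0.423 between the single mutant replicates and 0.463 between the double mutant replicates. The spread of that closest pair was 1.51 times the sampling noise, so they were not counted as 1 library deposited again. This does not show that they came from separate material.

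**Figure D3:**
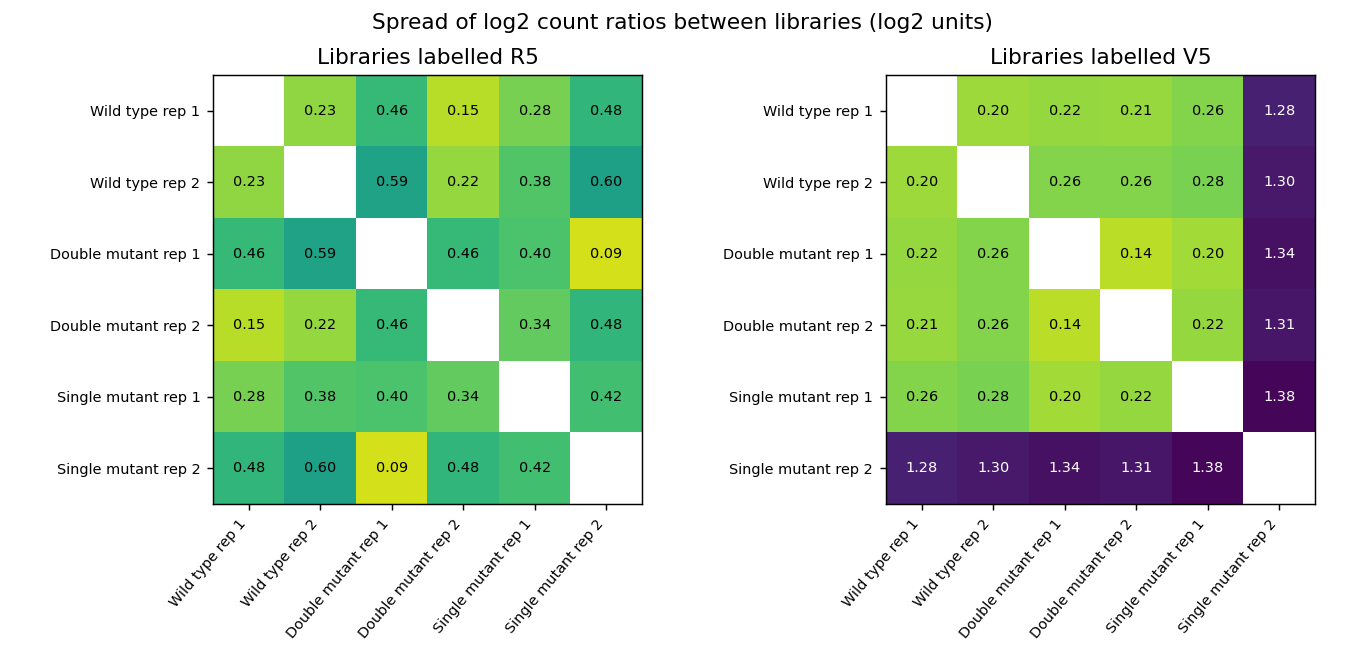
Spread of log2 count ratios, in log2 units, for each pair of libraries at R5 (left) and V5 (right). Each cell is 1 pair, and darker cells are larger. The single mutant replicate 2 lies 1.278 to 1.382 from the other V5 libraries, and the smallest R5 value, 0.089, joins a double and a single mutant library.

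At R5, Glyma.01G142400 was at 20.4 ± 1.6 CPM in wild type, 59.3 ± 7.99 CPM in the double mutant and 64.7 ± 0.421 CPM in the single mutant (SD, n = 2 each). Its log2 fold change was 1.65 (SE 0.17) in the double and 1.73 (SE 0.18) in the single mutant. Glyma.20G116700 was at 6.16 and 25.6 CPM in the wild-type libraries and at 0.0908 to 0.185 CPM in the 4 mutant libraries, with log2 fold changes of -6.73 (SE 0.9) and -7.15 (SE 0.92) in the double and the single mutant. Glyma.09G238100 averaged 16.2 ± 10.4 CPM in wild type, 0.411 ± 0.153 CPM in the double mutant and 0.939 ± 0.47 CPM in the single mutant (SD, n = 2 each). Glyma.01G204400 averaged 114 ± 93.6 CPM in wild type, 1.69 ± 1.23 CPM in the double mutant and 1.87 ± 0.73 CPM in the single mutant (SD, n = 2 each). These genes were chosen after their values were seen, and none passed edgeR's test (adjusted p 0.779 in the double and 0.585 in the single mutant).

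Over all genes at R5, edgeR called 0 of 37058 in the double mutant against wild type (1089 at an unadjusted p under 0.05) and 0 in the single mutant against wild type (2035 at an unadjusted p under 0.05). DESeq2 called 59 genes in the double mutant, 5 higher and 54 lower, and 76 in the single mutant, 28 higher and 48 lower. In DESeq2 the adjusted p of Glyma.01G142400 was 8.42e-10 in the double and 3.5e-11 in the single mutant. For Glyma.20G116700 the DESeq2 adjusted p was 3.66e-10 in the double and 3.5e-11 in the single mutant. It was 1.5e-09 for Glyma.09G238100 in the double and 3.5e-11 for Glyma.01G204400 in the single mutant. Simulated mutants that did not differ from wild type gave 79.2 and 75.6 DESeq2 calls on average, no fewer than observed in the double mutant and about as many in the single mutant. The mutants shared 43 DESeq2 calls in the same direction, 4 higher and 39 lower, where the simulation gave 17.4 and independent lists would give 0.00386 and 0.0714. The simulation does not hold the likeness of the close R5 pair, which has 1 library in each mutant group. With edgeR they shared 0. Limma with quality weights called 0 genes in either mutant. Without the close pair of libraries, a choice made after the data were seen, edgeR called 0 genes in the 3 R5 comparisons and DESeq2 called 25 in the double mutant, 166 in the single mutant and 59 between them, where simulated unchanged mutants gave 8 and 5.2 in the first 2. Each mutant is then 1 library, and the spread comes from the wild-type pair alone. With all 6 libraries the mutants differed from each other at 0 genes by edgeR (99 at an unadjusted p under 0.05) and at 0 by DESeq2 and by limma. Glyma.01G222600 had a log2 fold change of -1.19 (SE 0.34) between the double and the single mutant, with an edgeR adjusted p of 1.

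**Figure D4:**
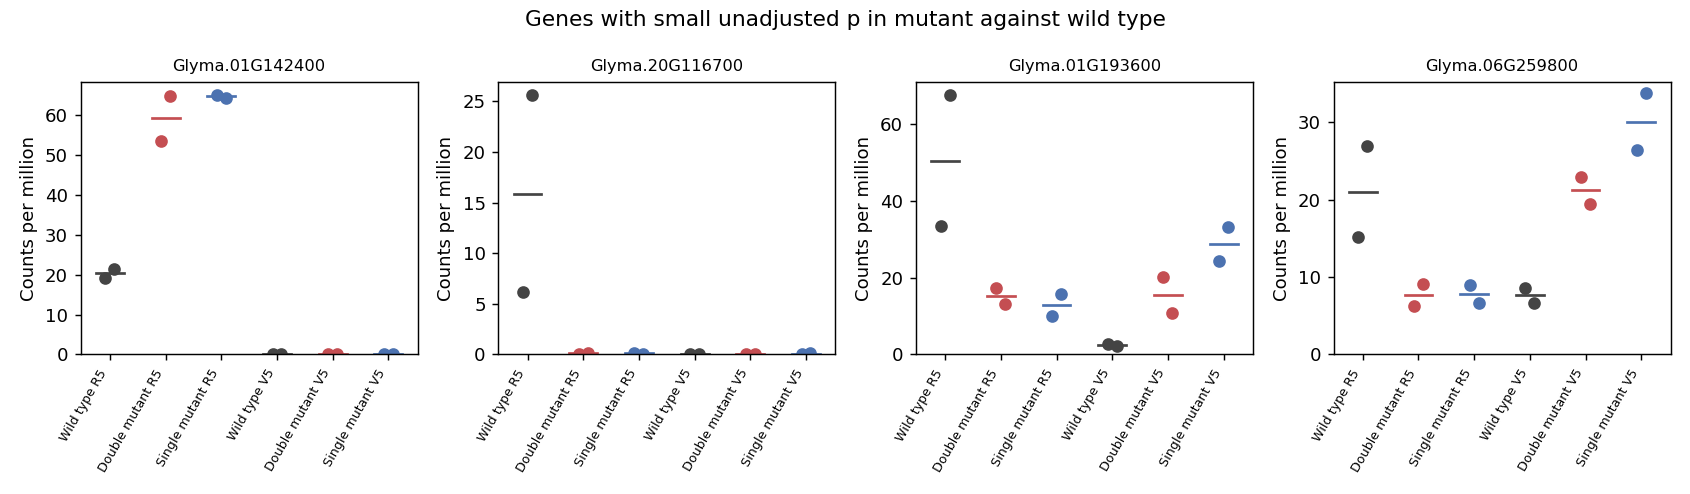
CPM values of 4 genes chosen after their values were seen, in wild type, double mutant and single mutant at R5 and V5. Points are libraries (n = 2 per group) and lines are group means. Glyma.01G142400 had 20.4 CPM in wild type and 59.3 and 64.7 CPM in the mutants at R5, and 0 counts in all V5 libraries.

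At V5, Glyma.01G193600 was at 2.69 and 2.19 CPM in the wild-type libraries, at 20.3 and 10.9 CPM in the double mutant and at 24.3 and 33.2 CPM in the single mutant. Its log2 fold change against wild type was 2.37 (SE 0.37) in the double and 3.11 (SE 0.38) in the single mutant. Glyma.18G294200 had a log2 fold change of 3.3 (SE 0.56) in the double mutant, and Glyma.06G259800 one of 1.55 (SE 0.22) in the single mutant. Both were also higher in the other mutant. Glyma.18G294200 was at 10.4 and 8.88 CPM in the single mutant against 1.57 and 0.536 CPM in wild type. Glyma.06G259800 was at 23 and 19.4 CPM in the double mutant against 8.57 and 6.68 CPM in wild type. Glyma.06G149100 was at 17.1 and 24 CPM in wild type and at 0.531 and 1.96 CPM in the double mutant, while the single mutant libraries had 13.9 and 33.5 CPM. Glyma.04G024400 was at 13.3 and 16 CPM in wild type and at 2.69 and 1.99 CPM in the single mutant, while the double mutant libraries had 11.9 and 14.6 CPM. Glyma.07G014500 had log2 fold changes of -4.74 (SE 0.54) in the single mutant against wild type and 3.34 (SE 0.51) in the double against the single mutant. It was at 9.51 and 14.8 CPM in wild type, 7.53 and 4.12 CPM in the double mutant and 0.577 and 0.665 CPM (12 and 14 counts) in the single mutant. These V5 levels were low beside the 8810 to 29000 CPM of this gene in the R5 libraries. Glyma.09G055100 was at 0.434 and 0.527 CPM in the double mutant and at 6.45 and 11.3 CPM in the single mutant. These genes too were chosen after their values were seen, and none passed edgeR's test (adjusted p 1 in the double mutant, 0.649 in the single mutant and 0.669 between the mutants). In DESeq2 on the same libraries the adjusted p of Glyma.01G193600 was 0.0062 in the double and 2.71e-06 in the single mutant. Against wild type it was 0.00141 for Glyma.18G294200 and 5.26e-05 for Glyma.06G149100 in the double mutant. In the single mutant it was 0.0032 for Glyma.06G259800, 2.83e-05 for Glyma.04G024400 and 6.64e-09 for Glyma.07G014500. Between the mutants it was 0.000928 for Glyma.07G014500 and 7.13e-08 for Glyma.09G055100.

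Over all genes at V5, edgeR called 0 of 33599 in the double mutant against wild type (517 at an unadjusted p under 0.05), 0 in the single mutant against wild type (2022) and 0 between the mutants (1351). DESeq2 called 9, 211 and 176, where simulated unchanged mutants gave 113 and 109.4 in the first 2, and limma with quality weights called 0 in each. The mutants shared 0 edgeR calls and 6 DESeq2 calls, where simulated unchanged mutants shared 21. That simulation gave all 6 libraries 1 pooled spread per gene, which the single mutant replicate 2 raised. Its counts are therefore not a level of no effect for the closer wild-type and double mutant pairs. The spread within V5 groups came mostly from the single mutant pair: the common coefficient of variation was 43.7% with all 6 libraries and 13% without either single mutant library, since the other then has no replicate. Without the single mutant replicate 2 edgeR still called 0 genes in each of the 3 comparisons, with a smallest adjusted p of 0.0529, 0.0878 and 0.0721, and 5594, 5541 and 3128 genes at an unadjusted p under 0.05. DESeq2 then called 595 genes in the double mutant, 428 in the single mutant and 36 between them, where simulated unchanged mutants gave 5.4 and 9 in the first 2. The mutants then shared 112 higher and 102 lower genes, where the simulation gave 0.2 in all and independent lists would give 1.93 and 2.15. The shared wild-type libraries are part of the simulation at the fitted spread, but not of the value for independent lists. A spread of the wild-type libraries beyond the fitted one could still add to the excess. Between the mutants DESeq2 then left the adjusted p of Glyma.07G014500, Glyma.04G024400 and Glyma.09G055100 undefined. Its count between the mutants leaves out such genes and cannot be set beside those against wild type. The DESeq2 fit without the single mutant replicate 2 was chosen after the data were seen. Its single mutant group is 1 library that is assumed to vary like the others. With the single mutant replicate 1 left out in its place, edgeR called 21539 genes against wild type and 22196 between the mutants, and DESeq2 called 609 genes in the double mutant, 15954 in the single mutant and 16436 between them.

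The difference of each mutant from wild type was then compared between the stages. Glyma.06G259800 was at 15.2 and 26.9 CPM in wild type at R5 and at 6.32 to 9.05 CPM in the 4 mutant libraries, while at V5 it was at 8.57 and 6.68 CPM in wild type and at 19.4 to 33.8 CPM in the mutants. The change of its log2 fold change, R5 minus V5, was -2.51 (SE 0.4) for the double and -2.91 (SE 0.41) for the single mutant, with edgeR adjusted p of 1 and 0.625. Glyma.13G356600 had a change of 2.38 (SE 0.5) for the double mutant and Glyma.02G146100 one of 2.46 (SE 0.44) for the single mutant, with edgeR adjusted p of 1 and 0.7. For both genes the other mutant's mean CPM was also above wild type at R5 and below it at V5. EdgeR called 0 of 38559 genes for the double mutant (981 at an unadjusted p under 0.05) and 0 for the single mutant (2645). DESeq2 called 16 and 132, and 118 and 125 without the single mutant V5 replicate 2. Without the single mutant V5 replicate 1 edgeR called 9713 genes for the single mutant.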

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

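All tests of explanations in this part were chosen after the result was seen.

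Some genes had both mutant libraries below both wild-type libraries at one stage and above them at the other. The change of the log2 fold change between R5 and V5 was -3.96 in the double and -4.98 in the single mutant for Glyma.01G193600, with edgeR adjusted p of 1 and 0.625 and DESeq2 adjusted p of 0.000586 and 3.31e-07. It was -2.51 in the double and -2.91 in the single mutant for Glyma.06G259800, with DESeq2 adjusted p of 0.000586 and 3.21e-06. In the double mutant it was -4.49 for Glyma.03G042700, 1.62 for Glyma.13G186500 and 2.38 for Glyma.13G356600, with DESeq2 adjusted p of 0.000179, 0.0706 and 0.0526 and edgeR adjusted p of 1 for each. In the single mutant it was 2.46 for Glyma.02G146100, with adjusted p of 0.7 in edgeR and 0.000569 in DESeq2. These genes had been picked for small p, so the test of the difference is not independent of the choice. Over all 38559 genes tested, in CPM without TMM scaling, 17.5% lay on opposite sides in the double and 10% in the single mutant. Chance gives 5.56%, and 8.42% and 8.4% lay on the same side at both stages. Wild-type TMM factors were above the double mutant's at R5 (1.22 and 1.248 against 1.081 and 1.17). They were below them at V5 (0.771 and 0.668 against 0.878 and 0.89). The single mutant had 1.271 and 1.079 at R5 and 0.817 and 1.15 at V5. Such offsets alone can put genes on opposite sides in the double mutant. At R5 the single mutant's factors lay on both sides of wild type's, so its 10% has no such offset at that stage. Both shares are in CPM without TMM scaling, so neither is read as an excess over chance.

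The single mutant V5 replicate 2 differed from the other V5 libraries, including its own replicate. Lower depth is argued against, since its total count was 1.02 times the mean of the other 5. A mixture with material like the R5 libraries is argued against as well. The 100 genes most abundant at R5 among those under 1 CPM in the other V5 libraries stood in it at a median of 0.000567 of their R5 level. Another part of the seed or another seed age remains open. A set of 343 genes was above 1 CPM in it and at 0.1 CPM or less in the other 5, where each other V5 library had 0 to 2 such genes. The opposite, 0.1 CPM or less in it and above 1 CPM in the other 5, held for 258 genes, where each other V5 library had 0 to 3. Without gene names these genes cannot be assigned to a tissue or an age.

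The double mutant R5 replicate 1 and the single mutant R5 replicate 2 were the closest R5 pair. A library deposited a second time is argued against, since their spread was 1.51 times the sampling noise and 21% of 14380 abundant genes lay beyond the 95% range of counting error. An exchange of labels between a double and a single mutant library could also give this: the libraries left over, double mutant replicate 2 and single mutant replicate 1, had a spread of 0.338 and were closer to each other than to their labelled replicates (0.463 and 0.423). It cannot be told apart from other causes, because the edited genes had at most 6 counts at R5 and give no mark of the genotype. Both libraries left over were closer to wild-type replicate 1 than to each other, double mutant replicate 2 at 0.149 and single mutant replicate 1 at 0.285. The value of 0.149 was also below the 0.235 between the wild-type replicates. An exchange between the mutants alone does not explain this. A shared plot, harvest day or seed age was not tested, since the labels give none.

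The V5 label names a stage without seed, and the V5 libraries were led by genes nearly absent at R5. Stage labels exchanged between the sets of libraries may be the reason: 8 of the 20 genes most abundant at V5 had 0 counts in all R5 libraries. This stays open, because the test needs the names of these genes, and the tables give IDs alone. Whichever way the labels belong, the comparisons between genotypes within a stage use the same libraries.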

How the results depend on the processing

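Fits with limma, with edgeR's newer dispersion method, without the single mutant V5 replicate 2 in DESeq2 or limma, without the close R5 pair (double mutant replicate 1, single mutant replicate 2) or with a term for it, and with crossed pairing were chosen after the data were seen. RLE size factors, no low-count filter, all 12 libraries, only the 4 libraries compared and the newer dispersion method gave 0 edgeR calls in the 6 comparisons within a stage, and 13806 to 15181 calls between the stages in wild type for those run there. The R5 fits without that pair and with a term for it also gave 0 edgeR calls, and limma on all 6 libraries of a stage gave 0 in each.

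DESeq2 called more genes: 59, 76 and 0 at R5 (double against wild type, single against wild type, double against single) with 43 shared between the mutants, 9, 211 and 176 at V5 with 6 shared, and 16 and 132 for the change between stages in the double and the single mutant. Unchanged simulated mutants gave 79.2 and 75.6 DESeq2 calls at R5 with 17.4 shared. The 59 calls lay below this, the 76 calls were about equal to it and the 43 shared calls lay above it. The simulation leaves out the likeness of the close R5 pair. At V5 it gave 113 and 109.4 calls with 21 shared, at 1 pooled spread per gene, which the single mutant replicate 2 raised. The V5 values are therefore not a level of no effect, and the observed V5 counts are not judged by them. Without the single mutant V5 replicate 2, DESeq2 gave 595, 428 and 36 calls at V5 with 214 shared, 118 and 125 for the change between stages and 21941 between the stages in wild type, and limma gave 23, 0 and 1. Without the close R5 pair, DESeq2 gave 25, 166 and 59 calls at R5 with 17 shared (simulated 8 and 5.2 with 0.8 shared). Each mutant is then 1 library, so these counts compare libraries, not genotypes. The cause was not tested. Without the single mutant V5 replicate 2, DESeq2 left the adjusted p of some genes undefined between the mutants. That count cannot be set beside those against wild type.

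With each library left out in turn, edgeR calls ranged from 0 to 21539 for the single mutant against wild type at V5, from 0 to 22196 between the mutants at V5, from 0 to 9713 for the change between stages in the single mutant, and from 7016 to 21813 between the stages in wild type. The first 3 maxima arose without the single mutant V5 replicate 1, which leaves the library that stands apart, assumed to vary like the others. The other counts and the shared calls stayed at 0.

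At V5, leaving out 1 library moved Glyma.20G085100 between -0.01 and 0.58 in the double and between -1.46 and 0.69 in the single mutant against wild type, and between -0.37 and 1.78 between the mutants, where 1.78, without the single mutant replicate 1, passed edgeR's threshold (adjusted p 0.027). It was 0.12 in the single mutant without wild-type replicate 2. Glyma.10G134400 moved between -1.19 and -0.77, between -0.76 and 0.75, and between -1.72 and -0.21. Without the single mutant replicate 2, Glyma.20G085100 was at 0.69 (DESeq2) and 0.68 (limma) in the single mutant and at -0.37 and -0.4 between the mutants. With limma on all 6 libraries Glyma.10G134400 was at -0.09 in the single mutant. The cause was not tested, and 10 to 67 counts per library limit these values.

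The replicate numbers did not pair the samples: the correlation of same-numbered deviations was 0.26, -0.35 and -0.72 at R5 and 0.06, 0.04 and 0.03 at V5. The replicate block gave 0 calls in the 6 comparisons within a stage and in both changes between stages, and 12762 between the stages in wild type. A crossed pairing of the R5 mutants gave 0 calls.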

Other observations

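The tests of a wild-type difference at each stage and of the neighbours of the edited genes were chosen after the result was seen, and the criterion of the first was revised then; the criteria of the correlation between stages and of the chromosome test were set before their values were seen, but leaving out the single mutant V5 replicate 2 in them was chosen after the data were seen.

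The likeness of the double and the single mutant differences from wild type rested on which libraries were used. The correlation across genes of the log2 differences was 0.87 at R5, where simulated unchanged mutants gave 0.5, with a covariance of 0.395 against 0.137 simulated. The close pair of R5 libraries puts 1 library in each mutant group, which the simulation does not hold. Without that pair the correlation was 0.35 against 0.33 simulated, and the covariance 0.101 against 0.074. In the same set, with 1 library per mutant, the mutants shared 17 DESeq2 calls against 0.8 simulated. With all 6 V5 libraries the correlation was 0.28 against 0.5 simulated, with a covariance of 0.125 against 0.235. The simulation gave these libraries 1 pooled spread per gene, which the single mutant replicate 2 raised, so 0.235 is not the value of no effect. Without the single mutant V5 replicate 2 the correlation was 0.71 against 0.41, with a covariance of 0.208 against 0.045. Both sets with libraries left out were chosen after the data were seen. Genes are not independent replicates, so these values carry no p.

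A hypothesis is that the wild-type libraries stand apart from the mutants. At V5 without the single mutant replicate 2, the wild-type pair lay outside the other libraries at 10581 of 29793 genes (35.5%, where chance gives 20%), and the highest of the other pairs reached 8151. The 10 pairs are too few for a share under 0.05. With all 6 V5 libraries the wild-type pair lay outside at 5049 of 30772 genes (16.4%, where chance gives 13.3%) and 3 of the 15 pairs had more, with 7700 the highest, for wild-type replicate 2 with the single mutant replicate 2. At R5 the wild-type pair lay outside at 7127 of 33925 genes (21%, where chance gives 13.3%), and 3 of the 15 pairs had more. The close double and single mutant libraries had 19356, and wild-type replicate 2 had 8340 with the double mutant replicate 2 and 7587 with the single mutant replicate 1. These splits do not follow the genotype labels. If labels were exchanged between a double and a single mutant library, which stays open, the one of 19356 could follow genotype, but those of 8340 and 7587 join wild type with a mutant and could not. The 7127 genes do not decide whether there is a genotype effect.

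A second hypothesis was that the mutants change the same genes at both stages. The correlation across 28133 genes of mutant minus wild type at R5 with that at V5, without the single mutant V5 replicate 2, was -0.009, and 137 of 150 pairings of splits gave one as large in size, with 0.167 the highest. With all 6 V5 libraries it was 0.136 across 28810 genes, and 111 of 225 pairings gave one as large, with 0.273 the highest. This argues only against a shared effect that is large beside the other differences between libraries. At R5 other pairs of libraries stood apart at more genes than the wild-type pair. A modest shared effect could therefore be missed, and a few shared genes remain possible.

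The next was that genes near the edited loci carry the differences. The share of genes with an unadjusted p under 0.05 on chromosomes 10 and 20 against the others gave odds ratios of at most 1.02 over 4 comparisons, those at V5 without the single mutant replicate 2 (Fisher's exact test, two-sided, adjusted p 0.941 for each). With all 6 V5 libraries they were 0.855 and 0.835 for the double and the single mutant (adjusted p 0.37 and 0.0604, Fisher's exact test). This argues against a chromosome-wide excess. Such a test would miss a short block. Among the 50 tested genes on each side of either edited gene the largest odds ratio was 1.12 (95% interval 0.76 to 1.62), for the double mutant at V5 without the single mutant replicate 2. The highest upper bound was 1.84, for the single mutant at R5, so a block of moderate size is not excluded.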
